A study of Mus musculus with 4 samples.

How the data were processed

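Per the submitters' processing notes, Cell Ranger 5.0.1 aligned the reads of a 10x Genomics 5′ V1.1 assay to mm10. The deposited files hold integer UMI counts for 32285 genes and 737280 barcodes per library, unfiltered, so the authors' own cell calls are not part of them. Whether the counting used the strand of the read is not given in the sources used here, so genes that overlap on opposite strands may share counts, and near-identical genes (H2-Q2, Gbp6, Gstp3, ribosomal proteins, receptor segments) may share reads. Coordinates are from GENCODE vM21 (GRCm38), joined on Ensembl identifiers, with 32235 genes matched. The floxed exons and the sequence of the Cd4-Cre transgene are not given in the sources used here.

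A barcode was kept as a cell with at least a 10th of the UMIs at the 99th percentile of the 5000 largest barcodes of its library (minimum 1893, 1901, 2263 and 2167 UMIs in WT 1, WT 2, dKO 1 and dKO 2), at least 500 genes and a mitochondrial share under 10%. The median mitochondrial share was 0.964, 2.27, 0.788 and 2.17%, and cells held 86.7, 66.4, 84.3 and 70.0% of all UMIs. Scrublet (through scanpy 1.11.5) scored doublets per library, and the highest scores were removed at 0.8% per 1000 cells: 251, 330, 255 and 485 barcodes. The threshold that scrublet sets by itself would have removed 2, 1, 0 and 0. No correction for RNA from other cells in the droplets was made.

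Counts were log-normalised, and 2000 variable genes were chosen in Seurat 5.3.0 without receptor, immunoglobulin, mitochondrial, ribosomal protein, Xist, Tsix and Y genes, Zfp148 and Zfp281. The 4 libraries were integrated by reciprocal PCA (30 components) and clustered by the Louvain method at resolution 1. Clusters were named by hand from the marker lists of the design, by the markers among the 10 genes of largest fold and by the number of markers detected, with genes ranked only where at least 25% of the cluster's cells held them. That minimum was set after a first ranking, in which hemoglobin and immunoglobulin genes of few cells led clusters 6, 10 and 17. A study with its own names may draw classes otherwise. Class names end in -like because only RNA names them. The mature SP list is a list of stage and not a competing class: it parts clusters 2 and 8 (mature) from clusters 1, 9 and 12 (immature), and cluster 2 was taken as CD4 SP-like for its Cd4 SP markers below the first 10 genes. Cluster 21, led by Mki67, was left unnamed for its median mitochondrial share of 7.19%; it holds 2, 76, 1 and 62 cells in WT 1, WT 2, dKO 1 and dKO 2.

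Counts were summed per library and class in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3) for classes with at least 20 cells in every library. Genes were tested in edgeR 4.0.16 (R 4.3.3) with the robust quasi-likelihood test, TMM scaling, filterByExpr, genotype alone as the model and Benjamini-Hochberg adjustment within each class, at an adjusted p of 0.05. Fold changes are log2 on the TMM scale, and CPM values are on total counts. The SE of an edgeR log2 is its absolute value over the square root of the quasi-likelihood F. It is thus taken back from the test, and log2 over SE does not give the p by itself. The difference of the effects in CD4 SP-like and CD8 SP-like cells was tested in edgeR as the class by genotype term, with library as a block. Fixed lists with at least 3 measured genes were tested by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over lists and classes, and again with an estimated correlation. "Over the list alone" means p-values adjusted among the members of that list. Lists fixed beforehand were the cell type markers (DN, cycling, quiescent DP, selected immature, strongly signalled, CD4 SP, CD8 SP, mature SP, regulatory T, innate-like, gamma-delta T, interferon, B cell, plasmacytoid), T cell receptor response, p53 and cell death, cholesterol synthesis, dissociation stress, ribosomal proteins, oxidative phosphorylation and lineage regulators. Erythroid, myeloid, NK or ILC and epithelial or stromal lists had fewer than 3 measured genes in each class and were not tested as lists, and their CPM are sums over all members.

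Shares were compared by an exact permutation test over the 6 assignments of libraries, and the share of each class by edgeR on cell numbers with the total of selected cells as library size. Intervals of a share are exact binomial 95% intervals and cover counting error only. In the 4 classes the replicates of a genotype differed beyond sampling (chi-squared per degree of freedom 4.13 to 10.6). Replicate numbers coincide with sex, mitochondrial share and RNA in empty droplets, and are not stated to mark a batch.

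Named genes follow a rule written beforehand. Zfp148 and Zfp281 come first in every library. Then come, per class, the 10 largest rises and 10 largest falls among genes past the threshold, with the same direction in all 4 pairs of libraries and a mean of at least 20 CPM. Up to 4 members of each fixed list follow by smallest p, and receptor segments are reported apart. Some list members that this rule names are not reported here. Gzma, Rora, and Zbtb7b, Thy1, Slc12a8, Platr23 and 4933409D19Rik in the closing section, were chosen after their values were seen, as were the genes named there for classes outside the 4 compared.

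The test was tried on counts drawn from the negative binomial distribution with the means, library sizes and dispersions of each class, with 200 genes given a known fold in the dKO libraries. Of 50 genes per fold, folds of 1.5, 2, 4 and 8 were found for 20, 60, 90 and 98% in quiescent DP-like cells (8663 genes tested), 24, 70, 94 and 94% in selected immature-like cells (9220), 36, 76, 86 and 100% in CD4 SP-like cells (10050), and 12, 54, 92 and 94% in CD8 SP-like cells (9227). Calls on genes that were not changed were 9.46, 6.62, 8.02 and 10% of calls, and 0 calls had the wrong sign.

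Alternatives tried were DESeq2 1.42.0, RLE size factors, no count filter, a replicate block, each library left out (the lone library of its genotype is then assumed to vary like the other 2), clusters without integration, a fixed minimum of 1000 UMIs, a mitochondrial share under 5%, no doublet removal, resolution 2, and fry for the lists. For many named genes the adjusted p was smaller with 1 library left out than with every library kept. Passing in such a fit therefore does not show that a call is steady. Classes rebuilt without the 2618 genes called in any of the 4 classes, with or without the block, were added after the first results were seen. Figures were drawn with matplotlib 3.10.9. Random steps used seed 1.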

Results

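Zfp148 and Zfp281 encode related zinc finger transcription factors, and the series asks whether the 2 redundantly support the development of CD4+ T cells. Thymocytes came from mice with floxed alleles of both genes, either without Cre recombinase (WT, 2 libraries) or with the Cd4-Cre transgene (dKO, 2 libraries). Cd4-Cre expresses Cre under Cd4 regulatory sequences, which are active from about the CD4+CD8+ double-positive (DP) stage. No library combined Cre with unfloxed alleles, and none lacked only 1 of the genes. Effects of Cre itself and of the transgene are therefore not separated from loss of the 2 genes, and redundancy is not tested. Sorted CD69+ cells, many of which recently received a T cell receptor signal, were mixed with CD69− DP and CD69− double-negative (DN) cells at 8:1:1 and profiled by 5′ droplet single-cell RNA sequencing. WT replicates 1 and 2 held 30007829 and 35773595 unique molecular identifiers (UMIs), and dKO replicates 1 and 2 held 35003231 and 49174803. After filtering, 5351 and 6094 WT cells and 5393 and 7299 dKO cells remained, with medians of 4056, 3005.5, 4450 and 3601 UMIs per cell. Replicate 1 was male and replicate 2 female in both genotypes, by Xist (the RNA of the inactive X chromosome) at 0.115 and 688 CPM (UMI counts scaled to the total of the library) in WT and 0 and 662 in dKO. The libraries of a genotype therefore come from different animals, and p-values within a class measure a spread that holds sex, animal and library preparation together.

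Clusters were named from marker lists fixed before the files were opened. Quiescent DP-like cells (cluster 0) were led by Rag1, which cuts receptor loci for recombination. Selected immature-like cells (clusters 4 and 6) were led by Egr1 and Egr2, early genes of receptor signalling, and by Tox and Ccr9. CD4 single-positive-like (CD4 SP-like) cells were clusters 1, 2 and 9, led by Cd40lg, Zbtb7b, S1pr1 and Klf2. CD8 single-positive-like (CD8 SP-like) cells were clusters 8 and 12, led by Itgae, Nkg7, Runx3 and Cd8a. Further clusters were DN-like (cluster 3; Il2ra), strongly signalled-like (cluster 5; Nr4a3 and Gadd45b), regulatory T-like (cluster 11; Ikzf4 and Ctla4), interferon-signature-like (cluster 13; Ifit3), cycling-like (clusters 14 and 16), innate-like (cluster 18; Ccl5), gamma-delta T-like (cluster 19; Sox13), B cell-like (cluster 20; Cd79a) and myeloid-like (cluster 22). Clusters 7, 10, 15, 17 and 21 were left unnamed. In WT 1, WT 2, dKO 1 and dKO 2 there were 734, 338, 603 and 413 quiescent DP-like cells and 783, 920, 748 and 954 selected immature-like cells. The same libraries held 1031, 1421, 1024 and 1682 CD4 SP-like cells and 436, 589, 482 and 715 CD8 SP-like cells.

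Zfp281 RNA was nearly gone from dKO CD4 SP-like and CD8 SP-like cells, and Zfp148 RNA was lowered by less. In WT 1, WT 2, dKO 1 and dKO 2, Zfp281 (ENSMUSG00000041483, chr1:136624901-136630053) stood at 38.4, 28.6, 36.0 and 23.5 CPM in DN-like cells, 53.6, 45.5, 13.02 and 3.87 in quiescent DP-like cells, and 84.1, 101, 13.2 and 1.81 in selected immature-like cells. In CD4 SP-like cells it stood at 157, 146, 5.44 and 2.23 CPM, and in CD8 SP-like cells at 56.4, 53.1, 3.55 and 1.94. Zfp148 (ENSMUSG00000022811, chr16:33380836-33504363) stood at 115, 90.7, 108 and 67.4 CPM in DN-like, 182, 137, 82.5 and 90.5 in quiescent DP-like, 105, 101, 54.4 and 64.5 in selected immature-like, 97.7, 91.6, 46.4 and 50.2 in CD4 SP-like, and 91.0, 85.1, 43.7 and 44.3 CPM in CD8 SP-like cells. Over all cells of a library, Zfp281 was at 78.0, 75.1, 12.4 and 5.75 CPM and Zfp148 at 106, 90.1, 58.2 and 50.6. Zfp281 fell in quiescent DP-like cells by log2 −2.40 (standard error, SE, 0.34; edgeR adjusted p = 0.0113), in CD4 SP-like cells by −5.22 (SE 0.23; 7.94e-05) and in CD8 SP-like cells by −4.23 (SE 0.28; 1.53e-08). In selected immature-like cells its log2 of −3.58 did not pass (SE 0.66; adjusted p = 0.280). The dKO libraries stood apart there, at 13.2 and 1.81 CPM. Zfp148 fell in quiescent DP-like cells by −0.86 (SE 0.16; 0.0310), in selected immature-like cells by −0.73 (SE 0.13; 0.0264), in CD4 SP-like cells by −0.84 (SE 0.11; 0.00345) and in CD8 SP-like cells by −0.91 (SE 0.15; 0.00112). With classes rebuilt from clusters made without any called gene, neither passed in quiescent DP-like cells (Zfp281 −2.71, SE 0.42, adjusted p = 0.167; Zfp148 −0.81, SE 0.17, 0.226). Nor did Zfp148 pass in selected immature-like cells (−0.62, SE 0.12, 0.0628). With a minimum of 1000 UMIs, Zfp281 did not pass in quiescent DP-like cells (−2.32, SE 0.39, 0.107) nor Zfp148 in CD8 SP-like cells (−0.49, SE 0.31). With DESeq2 Zfp148 did not pass in quiescent DP-like (0.248) and selected immature-like cells (0.207). Which part of either gene is floxed is not given in the sources used here, and a 5′ tag outside the deleted part checks nothing about the deletion.

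**Figure D1:**
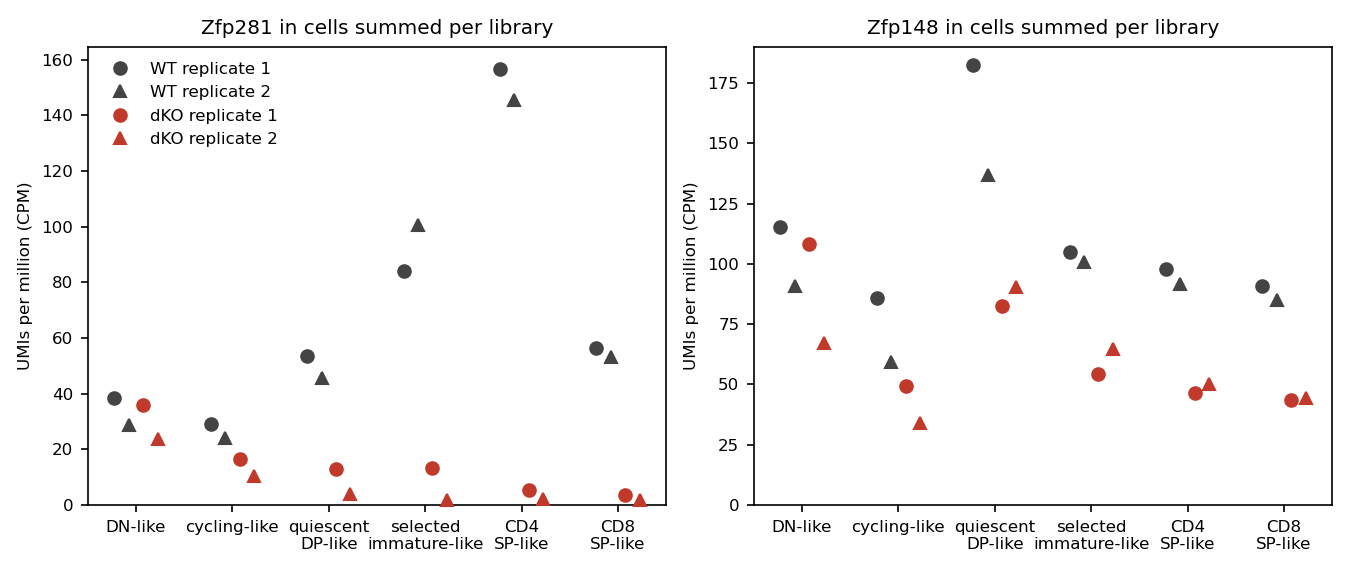
Zfp281 (left) and Zfp148 (right) in CPM, 1 point per library (circles replicate 1, triangles replicate 2; dark WT, red dKO), by cell class. Zfp281 was at 157 and 146 CPM in WT against 5.44 and 2.23 in dKO CD4 SP-like cells, and at 38.4 and 28.6 against 36.0 and 23.5 CPM in DN-like cells.

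In quiescent DP-like cells, Myc (ENSMUSG00000022346, chr15:61985391-61990374), a transcription factor that drives cell growth, rose from 20.5 ± 3.23 to 71.4 CPM (mean ± SD where given, n = 2 libraries per genotype here and below; log2 1.88, SE 0.24, edgeR adjusted p = 0.00349). Ptcra, which encodes the pre-T cell receptor alpha chain, fell from 72.8 ± 10.8 to 17.5 ± 10.5 CPM (log2 −1.95, SE 0.29, 0.0202). The chromatin remodelling gene Chd3 fell from 41.3 ± 17.7 to 5.81 ± 0.538 CPM (log2 −2.68, SE 0.39, 0.0110). Ikzf3, an Ikaros-family transcription factor gene, fell from 250 to 109 CPM (log2 −1.16, SE 0.14, 0.00349). Of 8837 genes tested, 13 rose and 29 fell in dKO (823 at an unadjusted p under 0.05). The other genes that rose the most were Dusp4, a phosphatase gene of MAP kinases (log2 1.87, SE 0.29, 0.0123), Wnt8b (1.49, SE 0.22, 0.0110), the interferon-induced GTPase gene Gbp6 (1.34, SE 0.15, 0.00349, 57.4 to 141 CPM), Syt13 (1.08), Insl5 (0.92), the glycolysis gene Eno1 (0.91, SE 0.12, 0.00637, 187 to 338 CPM), Dnajc7 (0.72), Ly6d (0.71, SE 0.11, 0.0126) and the histone gene H2afx (0.68). Besides these, the genes that fell the most were Zfp281, the sialomucin gene Podxl2 (log2 −1.52), Cxxc5 (−1.47, 77.6 to 26.5 CPM), Lrrc42 (−1.30, 148 to 58.2 CPM), the RNA-binding protein gene Rbm38 (−1.12, SE 0.13, 0.00349, 270 to 119 CPM), the polarity gene Patj (−1.09) and Anxa6 (−1.08). Ckb, the brain-type creatine kinase gene and a member of the CD4 SP list, fell from 20.7 to 0.814 CPM (log2 −4.25, SE 0.62, 0.0105), and 1 receptor segment, Trav8n-2, fell (−1.64). Markers of NK cells or innate lymphoid cells (NK or ILC) together stood at 45.5 and 82.8 CPM in WT and 93.9 and 142 in dKO. The granzyme gene Gzma was the 1 member tested (1.06, adjusted p = 0.487). Epithelial or stromal markers stood at 108 and 128 against 94.4 and 78.9. In the rebuilt classes 72.3% of all cells kept their class, and 0 genes passed, so every call here ended. Myc had a log2 of 1.28 (SE 0.33), Ptcra −2.20 (SE 0.50), Chd3 −2.37 (SE 0.31) and Ikzf3 −0.91 (SE 0.16), with adjusted p from 0.0655 to 0.462 over the genes named here. The number passing was 16 with DESeq2, 66 without integration and 158 without the count filter. Without dKO replicate 1 it was 9 and without dKO replicate 2 it was 12, against 154 and 174 without WT replicates 1 and 2. Of the 20 genes named by size, Myc, Gbp6, Zfp281, Ptcra and Rbm38 passed with any 1 library left out. Without dKO replicate 1, 14 of the 20 did not pass, without dKO replicate 2, 11, and without WT replicate 1, 1.

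Ribosomal protein genes, which build the ribosome, were higher as a group in dKO quiescent DP-like cells: of 90 measured, 0 rose, 0 over the list alone, and the median log2 was 0.24 (camera adjusted p = 1.49e-10, and adjusted p = 0.640 with an estimated correlation). Genes of oxidative phosphorylation, the respiratory chain and ATP synthase, were also higher (84 measured, 0 rose, median 0.15; 4.38e-05, and adjusted p = 0.640 with an estimated correlation). The interferon list (6 measured, 0 rose, median 0.52; 0.0445) was higher, with adjusted p = 0.756 with an estimated correlation. The plasmacytoid list (3 measured, Ly6d rose, median 0.71; 0.0226) was higher, with adjusted p = 0.640 with an estimated correlation. The mature SP list, a list of maturation stage (7 measured, 0 fell, 3 over the list alone, median −0.41; 0.0102), was lower, with adjusted p = 0.640 with an estimated correlation. The CD4 SP list (5 measured, Ckb fell, 2 over the list alone, median −0.35; 0.0169) and the strongly signalled list (3 measured, 0 fell, 2 over the list alone, median −0.85; 0.0445) were lower, each with adjusted p = 0.640 with an estimated correlation. The DN list had a median of 0.36 and a mean of 0.05 while the test pointed down, and made no call.

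In selected immature-like cells, Ckb (ENSMUSG00000001270, chr12:111669361-111672338) fell from 172 ± 16.6 to 16.3 ± 1.07 CPM (log2 −3.33, SE 0.15, edgeR adjusted p = 1.65e-07). Cd4, the coreceptor gene, rose from 148 ± 7.46 to 265 ± 6.10 CPM (log2 0.90, SE 0.10, 0.00184). The adhesion receptor gene Cd44 rose from 12.6 to 30.8 CPM (1.35, SE 0.22, 0.0153), and Eno1 from 322 to 587 CPM (0.93, SE 0.09, 0.000834). Of 9348 genes tested, 26 rose and 48 fell (931 at an unadjusted p under 0.05). The gene that rose the most was the long noncoding RNA Gm19705 (2.53, SE 0.33, 0.0147, 8.72 to 48.0 CPM), followed after Cd44 by Tsc22d1 (1.26, 0.00781), the coagulation factor gene F13a1 (1.24, SE 0.15, 0.00279, 32.7 to 74.5 CPM), Plekho1 (1.23), Ubtd1 (1.15), Dusp4 (1.03) and Gm11808 (0.92). After Ckb the genes that fell the most were the trypsin gene Prss2 (−1.67, 0.0372), Patj (−1.64, SE 0.22, 0.00501, 36.2 to 11.1 CPM), Itih5 (−1.32), the thromboxane receptor gene Tbxa2r (−1.24), the sialyltransferase gene St3gal6 (−1.19), Cxxc5 (−1.13), Lrrc42 (−1.10, SE 0.12, 0.00184, 119 to 53.4 CPM), Tiparp (−1.07) and Dusp5 (−1.03). Among list members, the integrin gene Itgb7, of the mature SP list, fell (−1.54, SE 0.26, 0.0207, 22.3 to 7.30 CPM), as did the early-response phosphatase gene Dusp1 (−0.86, 0.0340) and the segments Trbv5 (−0.69) and Trav7d-4 (−1.33). Gzma, of the NK or ILC list, rose (1.58, SE 0.28, 0.0212). It did not pass with DESeq2 (0.116) or with rebuilt classes (0.86, SE 0.31, 0.398). The list together stood at 12.7 and 12.5 CPM in WT and 23.3 and 34.1 in dKO. Leaving out WT 1, WT 2, dKO 1 or dKO 2 gave 107, 121, 87 and 52 genes, DESeq2 27, rebuilt classes 36 and no count filter 265. Of the 20 genes named by size, 11 passed with any 1 library left out, and 6 did not pass without dKO replicate 1, 5 without dKO replicate 2, 2 without WT replicate 2 and 1 without WT replicate 1.

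The ribosomal protein genes were higher as a group in dKO selected immature-like cells too (91 measured, 0 rose, 0 over the list alone, median log2 0.23; camera adjusted p = 1.2e-10, and adjusted p = 0.640 with an estimated correlation). So were the oxidative phosphorylation genes (83 measured, 0 rose, median 0.11; 0.00312, and adjusted p = 0.640 with an estimated correlation) and the interferon list (5 measured, 0 rose, median 0.30; 0.0445, and adjusted p = 0.756 with an estimated correlation). The CD4 SP list was lower (7 measured, Cd4 rose and Ckb fell, 2 and 2 over the list alone, median −0.08, mean −0.52; 0.000229, and adjusted p = 0.640 with an estimated correlation). The mature SP list (8 measured, Itgb7 fell, median −0.21; 0.0445) and the regulatory T list (3 measured, 0 fell, 2 over the list alone, median −0.31; 0.00721) were lower, each with adjusted p = 0.640 with an estimated correlation.

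In CD4 SP-like cells, the largest rise in dKO was in Gm19705 (ENSMUSG00000097113, chr1:136670769-136690804), a noncoding RNA, from 22.5 ± 4.28 to 336 ± 23.9 CPM (log2 4.03, SE 0.13, edgeR adjusted p = 3.02e-06). Myo6 (ENSMUSG00000033577), the gene of the motor protein myosin VI, rose from 28.1 ± 8.57 to 312 ± 49.8 CPM (log2 3.61, SE 0.25, 0.00213). The zinc finger gene Zfp467 (ENSMUSG00000068551, chr6:48427697-48445825) fell from 56.0 ± 2.63 to 1.44 ± 0.352 CPM (log2 −5.15, SE 0.21, 1.09e-05), and Ckb fell from 401 ± 4.93 to 22.4 ± 12.3 CPM (−4.06, SE 0.42, 0.0346). Ccr7, a chemokine receptor gene of maturing T cells, fell from 643 ± 89.6 to 318 ± 9.31 CPM (−0.89, SE 0.11, 0.00362). Cd4 rose from 287 ± 0.679 to 510 ± 18.9 CPM (log2 0.96, SE 0.08, 0.000858), in an assay that counts RNA and not surface protein.

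Of 10184 genes tested in CD4 SP-like cells, 280 rose and 359 fell (2050 at an unadjusted p under 0.05). The other genes that rose the most were Actn2, an actin crosslinker gene (log2 2.19, SE 0.18, edgeR adjusted p = 0.000777, 8.63 to 36.1 CPM), Plekho1 (1.90, 15.3 to 52.3 CPM), the antigen presentation genes H2-Ob (1.77, 0.00182) and H2-Q2 (1.46), Ctla2a (1.58), Anks1 (1.29), the steroid enzyme gene Akr1c18 (1.26, 0.0353) and Emid1 (1.26). The others that fell the most were Zfp281, the noncoding RNA Gm15708 (log2 −4.12, SE 0.19, 2.3e-05, 51.2 to 2.63 CPM), the TGF-beta family receptor gene Acvrl1 (−2.92, SE 0.20, 0.000777, 112 ± 24.4 to 13.4 ± 1.93 CPM), Zdhhc15 (−2.15), the transcription factor gene Sall2 (64.1 to 14.9 CPM), Igsf23 (−1.97), the tetraspanin gene Cd9 (−1.90, 40.1 to 9.84 CPM) and Card9 (−1.77). Among list members, Cd44 rose (1.09), Bbc3, a death gene of the p53 pathway, rose (1.04, SE 0.14, 0.00403, 27.3 to 51.1 CPM), and Runx1, a lineage regulator gene, fell (−0.59, SE 0.09, 0.00811, 132 to 79.9 CPM). Cd5, a brake on receptor signalling, fell (−0.58, SE 0.10, 624 to 381 CPM), as did the costimulatory gene Icos (−0.69, SE 0.11, 0.00805, 119 to 67.5 CPM), the early-response gene Dusp1 (−0.98, 0.0382) and the interferon pathway gene Ifit1 (−0.50). Nfkbid (0.72), Cd160 (1.63, 0.0191), Cd74 (0.77, 0.0444) and S100a10 (0.42, 0.0255) rose. Of the receptor segments, Trav9n-4 rose (1.28), and Trbv20 (−0.54), Trbv30 (−1.36), Trav1 (−0.89), Trav16n (−0.89) and Trav9-4 (−0.93) fell. Gata3 (0.28, adjusted p = 0.222) and Runx3 (0.45, 0.204), both of the lineage regulator list, and Cd40lg (0.06) did not pass. Zbtb7b, the master regulator gene of the CD4 lineage, is taken up in the closing section. Leaving out WT 1, WT 2, dKO 1 or dKO 2 gave 430, 525, 230 and 189 genes, and 16 of the 20 genes named by size passed with any 1 library left out. DESeq2 gave 387 genes and no count filter 1264. Ckb did not pass without WT replicate 1 (adjusted p = 0.349), WT replicate 2 (0.360) or the count filter (0.125). Epithelial or stromal markers together stood at 88.7 and 79.1 CPM in WT and 60.4 and 59.2 in dKO. Erythroid markers stood at 131 CPM in dKO replicate 2 and under 1 in the other libraries. Scaling on trimmed means shifted the log2 values of this class by 0.13 against total counts.

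The CD8 SP list was higher in dKO CD4 SP-like cells: of 7 measured members 2 rose, 3 over the list alone, and the median log2 was 0.54 (camera adjusted p = 0.000233, and adjusted p = 0.640 with an estimated correlation). Its members that rose were Dapl1, at 3.19 ± 0.456 and 15.5 ± 3.58 CPM in WT and dKO (log2 2.40, SE 0.27, edgeR adjusted p = 0.00201), and the coreceptor chain gene Cd8b1 (0.52, SE 0.11, 0.0302, 78.9 to 103 CPM). Cst7 (1.61, 0.124) and Cd8a (0.54) did not pass. Within the mature clusters alone Cst7 passed (2.27, 0.0361), and Cd8b1 had a log2 of 0.86 (0.00207) there and of 0.24 (0.459) in the immature ones. The CD4 SP list made no call (8 measured; Cd4 rose, Ckb and Icos fell; 0.345). The gamma-delta T list was higher (3 measured, 2 rose, 2 over the list alone, median 3.08; 4.62e-08, and adjusted p = 0.640 with an estimated correlation), with Sox13 (3.08, SE 0.24, 0.000763, 4.19 to 32.8 CPM) and the receptor gamma constant gene Tcrg-C1 (3.35, SE 0.46, 0.00481, 0.636 to 6.19 CPM). Of 94 ribosomal protein genes 28 rose and 1 fell, and 73 rose and 1 fell over the list alone (median 0.39; 1.59e-12, and adjusted p = 0.640 with an estimated correlation). Examples are Rplp1 (0.58, 0.00805), Rpsa (0.55, 0.00951), Rps12 (0.53, 0.00969) and Rps26 (0.50, 0.0131). Cholesterol synthesis genes were higher (13 measured, 1 rose, 2 over the list alone, median 0.38; 0.0220, and adjusted p = 0.640 with an estimated correlation), and the member that rose was Sqle (1.88, SE 0.35, 0.0165). Lineage regulators (0.505), p53 and cell death genes (0.770), T cell receptor response genes (0.788), dissociation stress genes (0.770), the mature SP list (0.431) and the interferon list (0.189) made no call. Median and mean log2 differed in sign for the strongly signalled (−0.23 and 0.04), p53 and cell death (−0.04 and 0.08) and DN lists (−0.16 and 0.06), which made no call. Nor did the cycling (0.806), quiescent DP (0.09999), selected immature (0.788) and innate-like (0.0722) lists.

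**Figure D2:**
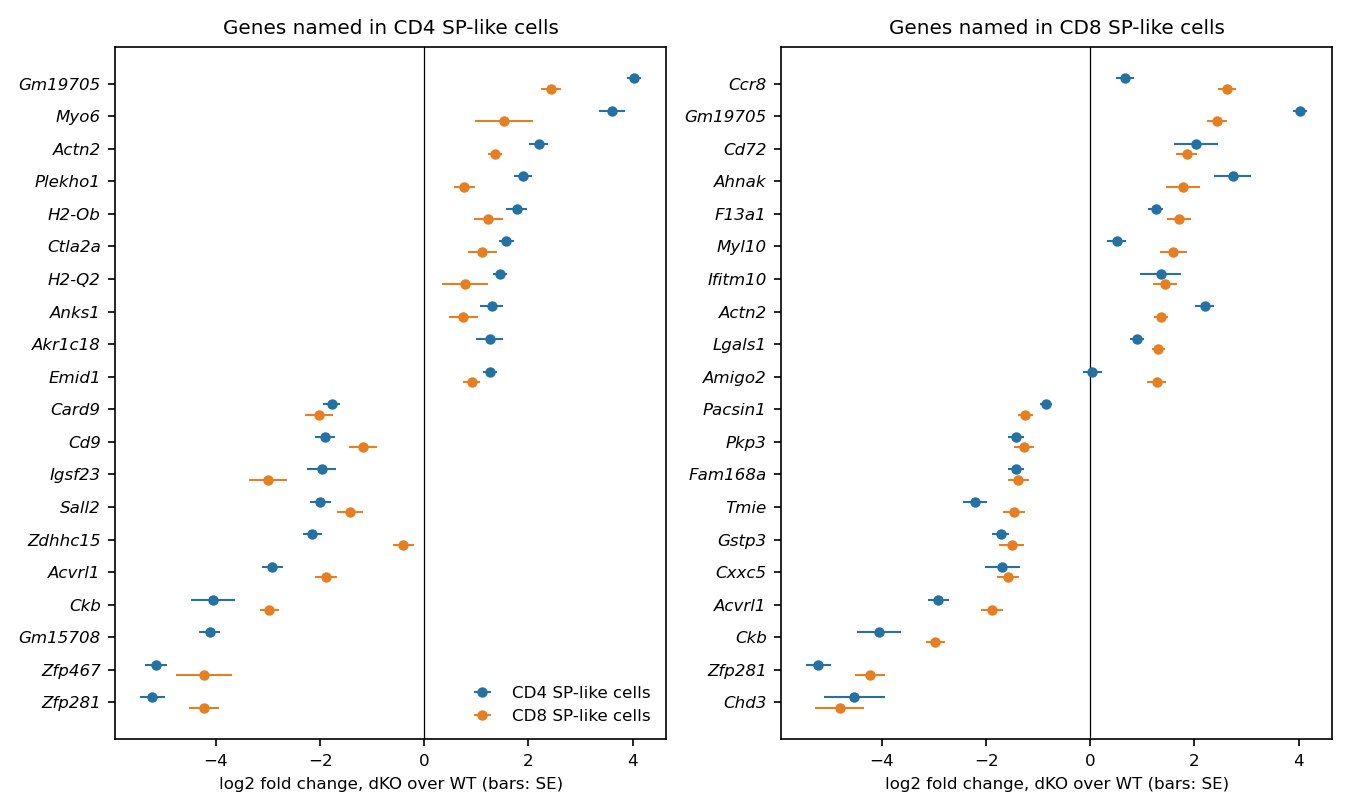
Log2 fold change in dKO over WT (horizontal axis, bars SE) for the 20 genes named by size in CD4 SP-like cells (left) and in CD8 SP-like cells (right). Blue points are CD4 SP-like and orange points CD8 SP-like cells; Gm19705 rose by 4.03 and 2.44, and Ccr8 passed in CD8 SP-like cells alone, at 2.62.

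In CD8 SP-like cells, Ccr8 (ENSMUSG00000042262, chr9:120092114-120094906), a chemokine receptor gene, rose from 18.1 ± 4.16 to 105 ± 2.67 CPM in dKO (log2 2.62, SE 0.18, edgeR adjusted p = 1.53e-08). Lgals1, which encodes the lectin galectin-1, rose from 180 to 420 CPM (1.30, SE 0.12, 6.59e-06), and Cd44 rose from 8.39 to 27.5 CPM (1.79, SE 0.26, 0.000439). Chd3 (ENSMUSG00000018474, chr11:69343273-69369406) fell from 204 ± 39.8 to 6.94 ± 5.24 CPM (log2 −4.81, SE 0.48, 0.0430). Id2, which encodes an inhibitor of E protein transcription factors, fell from 97.7 to 39.8 CPM (−1.21, SE 0.15, 8.91e-05). Of 9385 genes tested, 112 rose and 141 fell (1168 at an unadjusted p under 0.05). The others that rose the most were Gm19705 (2.44, SE 0.19, 2.06e-07, 14.4 to 73.7 CPM), the surface receptor gene Cd72 (1.85, SE 0.21, 2.51e-05, 18.6 to 63.1 CPM), Ahnak (1.78, 0.0151), F13a1 (1.70), the myosin light chain gene Myl10 (1.60), Ifitm10 (1.44), Actn2 (1.36, SE 0.13, 4.88e-06, 61.9 to 150 CPM) and Amigo2 (1.27). The others that fell the most were Zfp281, Ckb (−2.97, SE 0.18, 9.97e-09, 99.1 to 11.8 CPM), Acvrl1 (−1.89, 56.0 to 14.2 CPM), Cxxc5 (−1.58), the glutathione transferase gene Gstp3 (−1.51), Tmie (−1.47), Fam168a (−1.38), Pkp3 (−1.27) and Pacsin1 (−1.25, SE 0.15, 5.24e-05, 159 to 63.2 CPM). With 1 library left out, the adjusted p of many of the 20 genes named by size, Chd3 among them, was smaller than with every library kept. Passing in such fits is therefore no check on these calls. The number of genes passing was 435 without the count filter, 92 without integration, 77 without doublet removal, 59 with DESeq2 and 3 with a minimum of 1000 UMIs. There only Zfp281, Ckb and Chd3 passed, and Ccr8 had a log2 of 1.34 (SE 0.66). The class is another mixture of cells in that setting. It takes in a cluster of 1147 cells, and of those also in the main setting 29.8% were mature CD8 SP-like. Actn2 was among the 10 genes that set clusters 8 and 12 apart, and Ccr8 among those of cluster 9, so class membership may shape their values; with classes rebuilt without any called gene, their log2 was 1.25 and 1.66.

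Of the CD8 SP list in CD8 SP-like cells, 2 of 8 measured members fell, both among the genes that set these clusters apart, the integrin gene Itgae (log2 −0.50, edgeR adjusted p = 0.0338, 202 to 135 CPM) and the protease gene Ctsw (−0.41, 0.0465, 499 to 353 CPM), and the list made no call (camera adjusted p = 0.215). The activation genes Cd69 (−0.53, 0.0181, 186 to 121 CPM) and Egr2 (−0.72, 0.0379) fell, as did Dusp1 (−1.01, 0.0200), while Cd79b rose (0.99, 0.0171). Rora, a transcription factor gene of the NK or ILC list, rose (0.96, SE 0.21, 0.0151). It did not pass with DESeq2 (0.312) or with rebuilt classes (0.70, SE 0.17, 0.0737). The list together stood at 24.4 and 24.1 CPM in WT and 41.9 and 44.3 in dKO. Epithelial or stromal markers stood at 72.0 and 73.7 against 51.1 and 62.4. Of the receptor segments, Trav6-4 (4.67, SE 0.88, over 0 and 1 UMI in WT), Trav12-1 (1.10) and Trdv1 (1.28) rose, and Trbv5 (−0.94), Trav3-1 (−1.55), Trav7d-3 (−1.40), Trav13n-1 (−1.17), Trav4-4-dv10 and Trav8-2 (−1.94) fell. Cholesterol synthesis genes were higher (13 measured, 1 rose, 1 over the list alone, median 0.45; 0.000229, and adjusted p = 0.640 with an estimated correlation). Of 93 ribosomal protein genes 9 rose, 36 over the list alone (median 0.24; 3.15e-09, and adjusted p = 0.640 with an estimated correlation), among them Rplp1 (0.40), Rps12 (0.41), Rpl36 (0.42) and Rps19 (0.43). The CD4 SP list was lower (8 measured, Ckb fell, 2 over the list alone, median −0.03, mean −0.25; 0.00226, and adjusted p = 0.640 with an estimated correlation). The DN list was higher (3 measured, Cd44 rose, 1 over the list alone, median 0.16; 0.0360, and adjusted p = 0.640 with an estimated correlation). Lineage regulators (0.612), p53 and cell death genes (0.617), T cell receptor response genes (0.205), the interferon list (0.0739) and the B cell list (0.0555) made no call, and Bbc3 (0.82, 0.106) did not pass.

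Dapl1 rose more in CD4 SP-like than in CD8 SP-like cells, by a log2 difference of 2.34 (SE 0.33, edgeR adjusted p = 1.88e-05). Ccr8 rose more in CD8 SP-like cells (−1.97, SE 0.15, 2.38e-12): in CD4 SP-like cells its log2 of 0.66 did not pass. Ccr7 fell in CD4 SP-like cells and its log2 of −0.33 in CD8 SP-like cells did not pass (difference −0.58, SE 0.08, 2.22e-05). The palmitoyltransferase gene Zdhhc15 fell more in CD4 SP-like cells (difference −1.76, SE 0.24, 1.82e-05), and its log2 of −0.40 in CD8 SP-like cells did not pass. Id2 fell in CD8 SP-like cells, and its log2 of 0.20 in CD4 SP-like cells did not pass (difference 1.38, SE 0.22, 0.0381). Of 10245 genes tested for a difference between the effects, 113 passed, 51 with the larger log2 in CD4 SP-like and 62 in CD8 SP-like cells (919 at an unadjusted p under 0.05). Without WT 1, WT 2, dKO 1 or dKO 2 the number was 9, 3, 278 and 93. Of the 5 genes named here, Ccr8 alone passed with any 1 library left out. Of 9299 genes tested in both classes, 258 rose in CD4 SP-like and 109 in CD8 SP-like cells, 63 in both, where independent calls would give 3.02. For genes that fell the numbers are 326 and 134, with 98 in both against 4.70, and 0 changed in opposite directions. Part of the excess may come from the shared libraries, since both classes of a library come from the same mixture.

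CD4 SP-like cells made up 70.5 ± 0.295% of CD4 SP-like and CD8 SP-like cells in WT and 69.1 ± 1.54% in dKO, a difference of −1.41 percentage points (n = 2 libraries per genotype; exact permutation p = 0.33, the smallest that 6 assignments allow). Within replicates 1 and 2 the difference was −2.28 and −0.53 points. With clusters rebuilt without any gene called in the 4 classes the difference was −2.97 points, and with a minimum of 1000 UMIs it turned to 1.59 points. Cells of these same clusters were also sorted by their own Cd4 and Cd8 UMIs, after thinning every cell to 1800 UMIs. Among those with Cd4 alone or Cd8 alone, cells with Cd4 made up 42.5 ± 0.731% in WT and 52.2 ± 1.15% in dKO (9.70 points, and 50.3 and 57.7% before thinning). Cells with both or neither were left out. Neither was found in 52.6, 48.6, 34.0 and 32.5% of CD4 SP-like cells in WT 1, WT 2, dKO 1 and dKO 2. The measure follows the rise in Cd4 RNA. Mature clusters, led by S1pr1 and Klf2, were 38.7 ± 1.10% of CD4 SP-like cells in WT and 34.2 ± 2.24% in dKO (−4.50 points). Mature clusters were 60.8 ± 4.95% and 60.4 ± 2.08% of CD8 SP-like cells. Of 11 classes tested for a change of share among selected cells with edgeR, 0 passed (4 at an unadjusted p under 0.05, and no exact permutation p is under 0.33). The nearest were innate-like cells, led by Ccl5 and Klrb1c, at 2.53 ± 0.728% in WT and 1.23 ± 0.362% in dKO (log2 −1.06, SE 0.28, adjusted p = 0.0555), and cluster 15, at 3.15% and 4.59% (log2 0.55, 0.0555). With clusters rebuilt as above both passed (−1.11 and 0.50, each adjusted p = 0.0212), while innate-like cells had adjusted p = 0.102 without integration, 0.153 with a mitochondrial share under 5%, 0.293 without doublet removal and 0.411 with a minimum of 1000 UMIs (log2 −1.11 to −1.02). E2f1 and Mcm3 were among the leading genes of cluster 15, and 9 cycling markers were each found in at least 10% of its cells. Cycling-like cells, which were not among the classes tested, were 4.90% of all cells in WT and 6.17% in dKO. Of the other unnamed clusters, 7 held 8.69 and 9.02% of selected cells in WT and dKO, 10 held 5.32 and 5.37%, and 17 held 2.07 and 2.98%. Sorting fixed the mixture of CD69+, CD69− DP and CD69− DN cells, so these shares are not shares of the thymus.

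**Figure D3:**
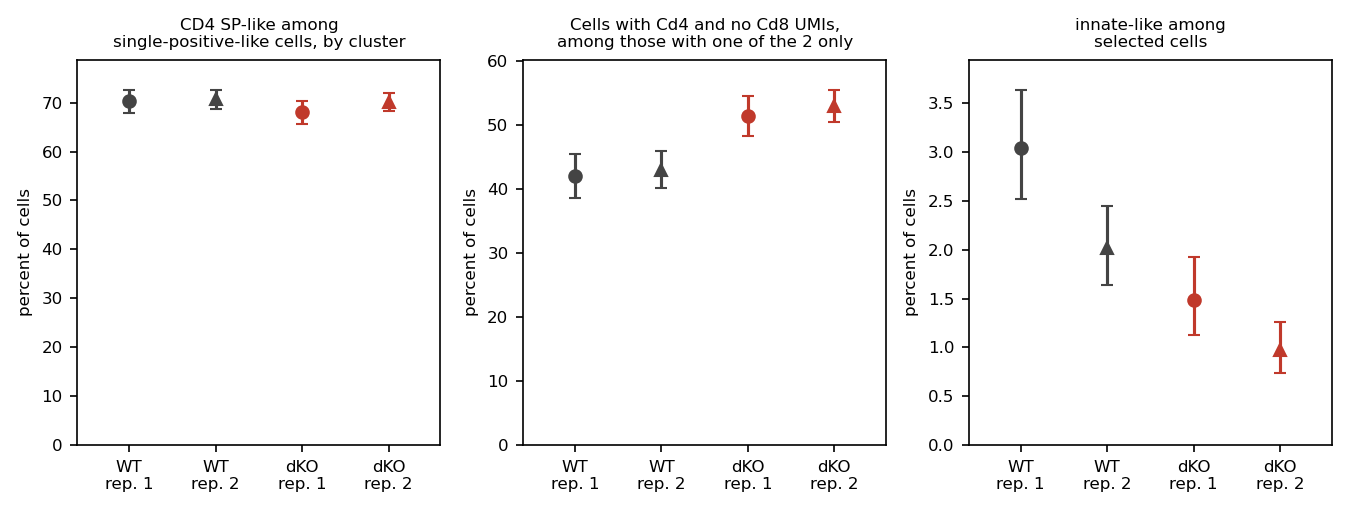
Percent of cells per library (vertical axis, bars 95% intervals of counting error alone, circles replicate 1, triangles replicate 2): CD4 SP-like among single-positive-like cells by cluster (left), cells with Cd4 and no Cd8 UMIs (middle) and innate-like among selected cells (right). The middle panel holds only CD4 SP-like and CD8 SP-like cells with UMIs of Cd4 alone or of Cd8 alone, after thinning. By cluster the 4 libraries lie at 70.3, 70.7, 68.0 and 70.2% (WT 1, WT 2, dKO 1, dKO 2).

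In DN-like cells, which precede the stage at which Cd4-Cre acts, 0 of 10053 genes passed with edgeR (101 at an unadjusted p under 0.05) and 0 with DESeq2. Of the 20 genes named by size in CD4 SP-like cells, 15 were measured there, with a median absolute log2 of 0.0757 (largest 1.04) against 1.90. In cycling-like cells 0 genes passed with edgeR (169 at an unadjusted p under 0.05) and 0 with DESeq2. Zfp281 stood there at 29.2, 24.2, 16.5 and 10.4 CPM in WT 1, WT 2, dKO 1 and dKO 2. Zfp148 stood at 85.7, 59.5, 49.5 and 33.8 CPM in the same order. In both classes the genes at an unadjusted p under 0.05 were fewer than evenly spread p-values would give. The edgeR test thus made few calls there even before adjustment. Nor was it tried on drawn counts in either class, so 0 calls do not show that no gene changed.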

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

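The tests of stage for Dapl1, of admixed cells for Cd8b1, of transcription running on past the deleted genes and of transgene reads at Cd4 were chosen after their results were seen, as were the named-gene exceptions Zbtb7b, Thy1, Slc12a8, Platr23, 4933409D19Rik, Gzma and Rora.

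The 29 genes of this paragraph stand out because the change in CD4 SP-like cells differed from the change in CD8 SP-like cells by a direct test of the difference in edgeR, and each value is that difference in log2, dKO over WT (edgeR adjusted p from 2.38e-12 to 0.0487). Leaving out WT 1, WT 2, dKO 1 or dKO 2 ended 24, 28, 4 and 11 of these calls, and Lrrc42 passed in none of the 4 fits. The CD8 SP gene Dapl1 differed by 2.34 and the coreceptor chain gene Cd8b1 by 0.64. Gm19705, beside Zfp281, differed by 1.57, and the motor protein gene Myo6 by 2.06. The chemokine receptor genes Ccr8, Ccr7 and Ccr9 differed by −1.97, −0.58 and 0.34. Regulators of transcription Id2, Id3 and Myc differed by 1.38, −0.44 and 0.44. The survival gene Bcl2 differed by 0.54, and the cytokine receptor gene Il2rb by 0.70. The surface protein genes Cd160, Ly6d, Cd74, Ms4a4b, Amigo2 and Tbxa2r differed by 1.28, 1.37, 0.66, −0.40, −1.25 and −0.69. The receptor kinase gene Acvrl1 differed by −1.04, the palmitoyltransferase gene Zdhhc15 by −1.76 and the galectin gene Lgals1 by −0.43. The cytoskeleton genes Actn2 and Myl10 differed by 0.82 and −1.11. Plekho1 differed by 1.11 and Lrrc42 by −0.59. The receptor segments Trav4-4-dv10, Trav6-4, Trav7d-3 and Trav8-2 differed by 1.27, −4.76, 2.03 and 2.20, and segments may mark clones of single libraries. The value of Trav6-4 rests on 0 and 0.439 CPM in WT CD8 SP-like cells and ran from −7.97 to −3.54 with 1 library left out. That of Ly6d ran from 0.62 to 1.66 and passed in 1 of 4 such fits, and its log2 did not pass in CD4 SP-like (1.44, SE 1.02) or CD8 SP-like cells (0.00, SE 1.24).

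The rise of Dapl1 and Cd8b1 in dKO CD4 SP-like cells could come from CD8 SP-like cells counted among them. Dapl1 would need 48.1% admixed cells, while the 20 genes most specific to CD8 SP-like cells need a median of 6.39% (quartiles 0.352 to 9.03%), so admixture alone likely leaves most of its rise unexplained. Of those 20, Actn2 (51.6%), Tnfrsf9 (33.6%) and Rgcc (30.1%) needed the most, and 4 needed less than 0. These shares use WT levels of CD8 SP-like cells, while admixed cells would be dKO cells, in which Actn2 rose too (log2 1.36). By stage, Dapl1 had a log2 of 2.77 within the mature clusters, where Cst7 (2.27, edgeR adjusted p = 0.0361) and Cd8b1 (0.86, 0.00207) passed too. Its rise is therefore seen among mature cells. In the immature clusters Dapl1 did not pass the count filter and was not tested. The mature clusters thus had to carry most of its counts, and this comparison by stage could hardly have come out otherwise. For Cd8b1 the test did not decide: it needs 1.49% admixed cells, while Cd8a needs 0.845%, Nkg7 0.416% and Itgae 0.161%, so a small admixture may account for part of its rise. The biological reading, weaker repression of some CD8 lineage genes in CD4 lineage cells without the 2 factors, was not tested on its own. Among members of the CD8 SP list it rests mainly on Dapl1, since Cst7 was not tested for admixture.

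The higher ribosomal protein level in dKO could be a difference between libraries that does not depend on Cre. In DN-like cells, which largely precede Cd4-Cre, the gain in ribosomal share was −0.103 and 0.240 of that in CD4 SP-like cells in replicates 1 and 2, under the level such a cause would likely give as the whole source, but the few B cell-like cells (19, 50, 31 and 55 in WT 1, WT 2, dKO 1 and dKO 2) gained −0.389 and 4.12 percentage points against 4.34 and 6.76 in CD4 SP-like cells, so a part from the libraries stays open in replicate 2. Deeper dKO cells are an unlikely cause as well, since matching CD4 SP-like cells on UMIs kept 0.876 and 0.761 of the gain. Classes in which Zfp281 RNA was lowered also differed in their gain. Innate-like cells, where Zfp281 stood at 20.9 and 28.4 CPM in WT and 0 and 0 in dKO, gained −0.101 and 2.27 points. Cluster 17 gained −0.522 and 1.76 points, while regulatory T-like cells gained 3.05 and 5.17 and CD8 SP-like cells 4.04 and 3.15. The gain therefore did not follow the loss of Zfp281 RNA in every class. An effect that begins after Cre acts remains a hypothesis, and other traits of the libraries were not separated from it.

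Genes at or beside the engineered loci may rise by way of the alleles themselves. Gm19705 starts 40.7 kb downstream of Zfp281 on its strand, and Slc12a8 (log2 3.20, SE 0.50, edgeR adjusted p = 0.00847 in CD4 SP-like cells) 13 kb downstream of Zfp148, while 0 of 6 other tested genes within 200 kb passed, and 2 genes with too few counts to test lay upstream of Zfp281 on the other strand and stood higher in both dKO libraries (Platr23 at 0.204 and 0.219 CPM in WT and 2.25 and 1.79 in dKO, 4933409D19Rik at 0 and 0 against 0.939 and 2.23). The gain of Gm19705 in CD4 SP-like cells was 2.08 times the WT level of Zfp281. That is more than running on of that transcript would likely supply if reads are counted alike. In quiescent DP-like cells, where Zfp281 fell, Gm19705 had a log2 of 0.05 (edgeR adjusted p = 0.986). Slc12a8, however, gained only 0.0429 of the WT level of Zfp148, as running on allows. Gm19705 did not gain in DN-like cells (−0.377 CPM), but Zfp281 was little changed there (log2 −0.15). Running on and lost repression both predict that, so DN-like cells cannot part them, and the test did not decide. Cd4 gained in quiescent DP-like cells 0.424 and 0.985 of what it gained in CD4 SP-like cells in replicates 1 and 2. In selected immature-like cells it gained 0.494 and 0.550 of that. These gains may come from Cd4 sequence in the transgene, and the test did not decide either. Lost repression by the 2 factors remains a biological reading. Telling it from these would need the sequence of the alleles and the transgene. Telling it from an effect of Cre itself would need cells with Cre and unfloxed alleles.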

How the results depend on the processing

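Classes rebuilt without called genes were added after the first results were seen, and the other alternatives were fixed beforehand. Rebuilt classes kept 72.3% of cells in their class, with 1 cluster taken as CD4 SP-like and 1 as CD8 SP-like by leading shares of 37.1 and 35.9%, and a minimum of 1000 UMIs kept 86.4%, so calls are compared there over other mixtures of cells. Of 144 named gene calls past the threshold and 3 named genes that did not pass, none reversed direction under the alternatives run for them. Other named genes that did not pass, and genes of classes outside the 4 compared, were not checked. Of 144 named gene calls past the threshold, 56 did not pass with DESeq2, 1 with RLE size factors, 1 without the count filter, 16 with a mitochondrial share under 5%, 17 at resolution 2, 35 of 143 without doublet removal, 32 of 143 without integration, 61 of 143 with a minimum of 1000 UMIs and 62 with rebuilt classes. Leaving out WT 1, WT 2, dKO 1 or dKO 2 lost 28, 22, 58 and 54 of them, among them Slc12a8 in CD4 SP-like cells without dKO 2 (0.0878). Of the 29 differences between CD4 SP-like and CD8 SP-like cells, RLE lost 4, and leaving out WT 1, WT 2, dKO 1 or dKO 2 lost 24, 28, 4 and 11.

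Genes changed in quiescent DP-like cells numbered 42, and 16 with DESeq2, 66 without integration, 158 without the count filter, 0 with rebuilt classes (668 at an unadjusted p under 0.05) and 9 to 174 with 1 library left out. In selected immature-like cells they numbered 74, and 27 with DESeq2, 265 without the filter, 36 with rebuilt classes and 52 to 121 with 1 library left out. In CD4 SP-like cells they numbered 639, and 387 with DESeq2, 1264 without the filter and 189 to 525 with 1 library left out. In CD8 SP-like cells they numbered 253, and 59 with DESeq2, 435 without the filter, 92 without integration, 77 without doublet removal, 3 with a minimum of 1000 UMIs and 240 to 283 with 1 library left out. The 113 differences between the classes became 3 to 278. With 1 library left out fewer samples enter the fit, yet the number also rose in some of these fits, and the cause of the moves was not tested.

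Within the 4 classes, libraries of the same number deviated together from their genotype's mean (correlation 0.334 to 0.476, and 0.239 to 0.351 without sex genes), but the labels state no pairing and 2 pairs are too few to show one. The replicate block gave 419, 374, 2293 and 663 genes in quiescent DP-like, selected immature-like, CD4 SP-like and CD8 SP-like cells, held 42, 74, 639 and 251 of the calls above, and gave 24 in DN-like and 71 in cycling-like cells. With it the lists strongly signalled (0.0601) and CD4 SP (0.0780) in quiescent DP-like, mature SP (0.0738) in selected immature-like, cholesterol synthesis (0.0552) in CD4 SP-like, and DN (0.0610) and CD4 SP (0.0722) in CD8 SP-like cells did not pass. The quiescent DP list in quiescent DP-like cells reversed its sign without a call (0.953), and 13 further lists passed. Innate-like cells had a log2 of −1.04 with the block (adjusted p = 0.0259). Zbtb7b (−0.70) and Thy1 (−2.15) in CD4 SP-like cells and cluster 15 (0.0313) passed with the block. Among the named genes checked, 144 past the threshold and 3 not, and among the shares, the block changed no other call. Other named genes that did not pass were not checked with the block, and the cause was not tested.

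None of the 21 list calls passed with an estimated correlation (adjusted p 0.640, and 0.756 for the interferon list) or with fry. With fry, in quiescent DP-like cells, strongly signalled and CD4 SP gave 0.221, mature SP 0.436, interferon 0.614, plasmacytoid 0.352, ribosomal proteins 0.294 and oxidative phosphorylation 0.328. In selected immature-like cells CD4 SP gave 0.221, mature SP 0.440, regulatory T 0.288, interferon 0.607, and ribosomal proteins and oxidative phosphorylation 0.328. In CD4 SP-like cells CD8 SP gave 0.283, gamma-delta T and ribosomal proteins 0.221 and cholesterol synthesis 0.253. In CD8 SP-like cells DN, cholesterol synthesis and ribosomal proteins gave 0.221 and CD4 SP 0.328. The cause was not tested.

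The share of CD4 SP-like among single-positive-like cells differed by 1.59 points with a minimum of 1000 UMIs, −2.97 with rebuilt classes and −2.49 to −0.32 with 1 library left out. By thinned UMIs, among those of these cells with Cd4 alone or Cd8 alone, it differed by 9.70 points. The innate-like log2 was −1.11 with rebuilt classes (adjusted p = 0.0212), −1.11 to −1.02 without integration, with a mitochondrial share under 5%, without doublet removal or with a minimum of 1000 UMIs (0.102 to 0.411), and −1.35 to −0.74 with 1 library left out, where it passed without dKO 1 (−1.35, 0.0412) and without WT 2 (−1.34, 0.00647). Cluster 15 passed with rebuilt classes (0.50, 0.0212). The log2 share of interferon-signature-like cells reversed from −0.42 (SE 0.16, unadjusted p = 0.0264) to 0.558 without integration (SE 0.22), without passing in either. Log2 shares near 0 reversed too: cluster 10 (−0.00500 at resolution 2, −0.134 without integration, −0.327 to 0.279 with 1 library left out), cluster 7 (−0.0231 to 0.134), CD4 SP-like (0.0414 with 1000 UMIs, −0.0667 to 0.0416), CD8 SP-like (−0.0863 with 1000 UMIs), regulatory T-like (−0.0241 to 0.175) and selected immature-like (5.64e-05 with rebuilt classes). The cause was not tested.

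DESeq2 was not run for the difference between classes, and a block there was not possible because library is already a block. At a fold of 1.5 the test found 12 to 36% of changed genes in drawn counts, and the part of depth in this was not tested.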

Other observations

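Zbtb7b, the master regulator gene of the CD4 lineage, was named after its values were seen. In CD4 SP-like cells it went from 126 ± 16.1 to 72.0 ± 23.7 CPM in dKO without passing (log2 −0.69, SE 0.21, edgeR adjusted p = 0.146, and 0.0363 with DESeq2). Zbtb7b was among the 10 genes that set clusters 1 and 9 of this class apart, so class membership may shape its values there. It fell in regulatory T-like cells (−1.33, 0.00937; 73.6, 51.8, 27.7 and 19.2 CPM in WT 1, WT 2, dKO 1 and dKO 2). In cluster 7, which holds both Cd4 and Cd8 RNA, it fell by log2 −2.50 (0.0231). Thy1, a surface protein gene of T cells, had a log2 of −2.12 in CD4 SP-like cells without passing (edgeR 0.102; DESeq2 0.000587), and its change differed from that in CD8 SP-like cells (1.31e-07). Without dKO replicate 1 both passed (Zbtb7b 0.0151, Thy1 0.00532), and without dKO replicate 2 Thy1 passed (0.00126) and Zbtb7b had a log2 of −0.40 (0.261) against −1.02 without dKO replicate 1. In these fits the spread comes from the WT libraries alone. Without WT replicates 1 and 2 neither passed (Zbtb7b 0.498 and 0.336, Thy1 0.445 and 0.501), and without the count filter Zbtb7b passed (3.93e-07). Both genes were chosen after their values were seen.

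Outside the 4 compared classes, genes that changed there repeat in part. Those given here were chosen after their values were seen, from the genes that the same rule names. In cluster 7, 73 genes rose and 83 fell with edgeR: Gm19705 (log2 3.70), Myo6 (2.93), Cd44 (2.01) and Ccr8 (1.99) rose, and Zfp467 (−5.37), Ckb (−4.37), Chd3 (−3.90) and Acvrl1 (−2.46) fell. In regulatory T-like cells 85 rose and 55 fell: Gm19705 (3.30), Dapl1 (2.98), Pdzk1ip1 (2.43), the chemokine gene Xcl1 (2.24) and Cd72 (2.11) rose, and Ckb (−3.47) and the checkpoint gene Vsir (−1.30) fell. In interferon-signature-like cells 53 rose and 83 fell, with Myo6 (4.04) and Gm19705 (2.89) up and Chd3 (−4.79) and Zfp467 (−4.63) down. In strongly signalled-like cells 7 rose and 21 fell, with Gm19705 (3.75) and Cd160 (0.92) up and Ckb (−2.47) down. In cluster 17, 7 rose and 27 fell, with the actin gene Actg2 (2.23) and Slamf6 (1.21) up and the myosin gene Myl1 (−3.43), Runx3 (−1.64) and Fcer1g (−1.55) down. In cluster 15, 3 rose and 4 fell, with Akr1c18 (6.56) and Myo6 (4.68) up and Ypel3 (−1.79) down. In cluster 10, 7 rose and 24 fell, with Tsc22d1 (1.61) and Phlda1 (1.55) up and Ckb (−3.91) down. In innate-like cells 4 rose and 0 fell, among them the chemokine gene Ccl5 (1957 and 1622 CPM in WT, 4766 and 4979 in dKO), Lgals1 (1.31) and Eno1 (1.27). In gamma-delta T-like cells Gm20400 rose (1.82).

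By stage, 159 genes rose and 224 fell in immature CD4 SP-like cells and 265 rose and 227 fell in mature ones, with edgeR, while 96 passed in immature and 74 in mature CD8 SP-like cells. Cells of cluster 21, led by Mki67, came almost all from replicate 2, with 2, 76, 1 and 62 cells in WT 1, WT 2, dKO 1 and dKO 2. The hemoglobin gene Hba-a1 was at 20.4, 0, 219.9 and 12.3 CPM in the cells of WT 1, WT 2, dKO 1 and dKO 2. In CD4 SP-like cells the erythroid genes together were at 131 CPM in dKO 2 and under 1 in the other libraries.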
